A study of Mus musculus with 6 samples.

How the data were processed

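CD8 T cells from CT26 tumours grown in BALB/c mice were measured by droplet single-cell RNA sequencing (10x Genomics 3′ v3 chemistry) together with oligonucleotide-tagged antibodies (TotalSeq-A, the CITE-seq method, in which an antibody's tag is counted like a transcript). Cells that bound a tetramer of H-2Ld and a gp70 peptide strongly, weakly or not at all were sorted as Tet-High, Tet-Low and Tet-Negative. Tumours of 15 mice were pooled before each sort, and the 2 pools gave 6 libraries, 2 per group. The sample number in the titles (replicate 1 or 2) was read as the pool from which the 3 fractions of a sort came, which the labels do not say outright. Libraries of one number were paired in comparisons within a pool and in alternative fits with the pool as a block. The main fits held no pool term. In a check over 6708 well-measured genes, the deviation of a library from its group mean correlated across genes with that of the same-numbered library by 0.85 for Tet-High and Tet-Low, 0.37 for Tet-High and Tet-Negative and 0.41 for Tet-Low and Tet-Negative. Genes are not independent replicates, so these values describe the pairing without a test.

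The deposited matrices held raw UMI counts per gene and cell barcode for 31053 mouse genes, and the deposited antibody files held UMI counts per tag and barcode for 436 tag names plus unmapped tags. The matrix headers named Cell Ranger 3.0.2. The submitters' processing notes named Cell Ranger and Seurat without a version or a role. The genome build and gene annotation were not given in the sources used here, so genes are named by the symbol and Ensembl identifier of the matrices without coordinates.

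Barcodes with at least 500 genes and at most 10% of UMIs on mitochondrially encoded genes were kept, 20694 of 23345. Scrublet marked 15 barcodes as doublets, 0.064% of all, below the 0.5% set as the least for its use, so no doublet caller was applied. Counts were scaled to 10000 per cell and logged. A set of 2000 variable genes without T cell receptor segments was centred per pool and reduced to 30 principal components, and cells were clustered with Leiden at resolution 1.0 on 15 neighbours (seed 1). Leading genes were ranked by fold over the other clusters with an offset of 20 CPM. A cluster was left out as another cell type when at least 3 of its 10 leading genes were markers of that type. It was named as a CD8 T state when at least 2 of its 10 and 3 of its 30 leading genes were markers of the state and no other type had as many. Of 20 clusters, 3 were led by markers of other cell types (natural killer, dendritic, and macrophage or monocyte), and their 244 cells were left out. A further 7 stayed unnamed. The macrophage or monocyte cluster held Cd8a at 669.2 and Cd3e at 473.6 CPM and a median of 20301 UMIs. Doublets of macrophages with CD8 T cells were not told apart from macrophages there. The 20450 retained CD8 T cells entered every sum.

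UMI counts were summed per library over the retained cells, and all 3 groups were fitted together with edgeR 4.0.16 (quasi-likelihood F test, TMM size factors, filterByExpr), because cells are not replicates and 2 libraries per group leave few degrees of freedom. The contrasts were Tet-High minus Tet-Negative, Tet-Low minus Tet-Negative and Tet-High minus Tet-Low. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called higher or lower. The edgeR p-values rest on the spread between libraries of a group, shared in part over the items tested together. That sharing counts items as independent, although tags or cell classes of a library share its scaling. The p-values of tags and classes may thus be smaller than the spread between pools alone would give. A permutation of 2 against 2 libraries could not reach the threshold. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM are UMI counts scaled by the TMM library size, given as mean ± SD of 2 libraries. The same test was run on antibody tags (13 antibodies with at least 1 UMI per cell in some library, TMM over antibodies), on numbers of cells per class, on UMI counts of 20 Trbv genes, and on sums within each named class that had at least 50 cells in every library.

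The lists of genes were inhibitory receptors, exhaustion transcription factors, naive and central memory, progenitor exhausted, cytotoxic granule, cytokines and chemokines, TCR activation, proliferation, type I interferon response, glycolysis, oxidative phosphorylation, tissue residency, effector memory, NK-type receptors, immediate early and heat shock, MHC class II and myeloid genes, and mitochondrially encoded genes. Each was tested with camera (limma 3.58.1) at an inter-gene correlation of 0.01, adjusted over all lists and contrasts, and members were counted with adjustment over all genes and over the list alone. At that fixed correlation camera takes genes as nearly independent, so its p-values do not measure the spread between pools. Several genes stand on 2 lists, and Fcer1g and Tyrobp stand on both the NK-type and the MHC class II and myeloid list. Genes were named by rule: per contrast the 10 highest and the 10 lowest log2 fold changes among called genes with a mean of at least 10 CPM and one direction in both pools, without predicted genes, ribosomal protein genes and receptor segments, plus list members, the 5 highest and 5 lowest proteins, and Cd8a, Cd8b1, Cd3e and Cd4 as checks of the sort. A gene and its protein that came under this rule are not reported here. Lists, tests, filters and the naming rule were chosen before the data were examined. The marker thresholds of cluster names, the minimum of 1 tag UMI per cell, the test of an unnamed cluster by its number, and a clustering without the 7610 genes called against Tet-Negative were chosen after seeing the data. That last clustering gave 11 clusters, of which 10 were tested. The other held 6 retained cells led by mast cell and stromal genes, which stayed in the sums. This clustering replaced the planned classes as the source of tested cell shares, since the planned clusters rest on the genes that separate the groups. Genes that differed without a call stayed in it, so its clusters may still rest in part on differences between the groups.

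The position of Tet-Low between the other groups was measured without a test. The 100 genes most raised and the 100 most lowered in Tet-High against Tet-Negative (mean of at least 20 CPM) were chosen in one pool, and the median difference of Tet-Low over that of Tet-High was taken in the other pool. All differences were of log2 CPM with 1 added, so the positions are on a log2 scale. Simulated positions of 0.25, 0.5, 0.75 and 1.0 came back as 0.26 to 0.29, 0.49 to 0.51, 0.72 to 0.77 and 0.99 to 1.04. That simulation held no effect of pool and put every gene of Tet-Low at the same position. In the data Tet-High and Tet-Low of a pool deviated together (correlation 0.85), so these ranges hold for the simulated setting alone.

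Retained cells held 33387906 and 46415711 UMIs in the Tet-High libraries of pools 1 and 2, 29613935 and 41061411 in Tet-Low, and 33547332 and 36210669 in Tet-Negative. Unmapped tags took 3.41 to 3.95% of tag UMIs in pool 1 and 11.62 to 15.8% in pool 2. The CD8b tag stood at 4.02, 5.43 and 4.48 UMIs per cell in Tet-High, Tet-Low and Tet-Negative of pool 1 and at 33.5, 29.1 and 33.4 in pool 2, which bears on tag means and SDs over the pools. Whether the antibody panel and the tag sequencing were alike in both pools is not given in the sources used here. Across 6708 genes, log2 CPM of the 2 libraries of a group correlated with r of 0.988 to 0.989, and the chi-square of their counts per gene was 54.4 to 73.2, so counting noise was a small part of the spread. Counts were simulated from the mean CPM of each gene over all libraries, the real library sizes and the fitted dispersion. For each size of fold, 66 or 67 genes were changed. The simulation held no effect of pool and far fewer changed genes than were called in the data, so its rates hold for that setting alone. The pipeline was tested on these simulated counts. It called 68.7 to 73.1% of genes changed by 1 on the log2 scale, 7.6 to 12.1% of those changed by 0.5 and 91 to 92.5% of those changed by 2, and 4.1 to 5% of its calls were unchanged genes. Binomial intervals are exact at 95% confidence, and intervals and limits of a count of 0 (3 counts) cover counting error alone.

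Alternatives were the pool as a replicate block, RLE size factors, DESeq2 1.42.0, no filter on low counts, all barcodes, equal numbers of cells (2541 per library), at most 5% mitochondrial UMIs, no cycling cells, each library left out in turn, camera with an estimated correlation, fry, other scalings of the tags, and Leiden resolutions of 0.5 and 1.5. Sums without naive-like cells, sums without the top 5% of cells by UMIs, the number of cells as tag library size, and every tag that passed the count filter were added after seeing the data. Other tools were R 4.3.3, Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The unmapped tags, the 9 isotype controls and the streptavidin tag were left out of the protein test, the isotype controls serving as background.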

Results

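Tumour-infiltrating CD8 T cells were compared by how strongly they bound a tumour antigen. The tumours grew from CT26, a colon carcinoma line of BALB/c mice, and the tetramer used for sorting carried a peptide of gp70, an envelope protein of an endogenous retrovirus that CT26 cells express. Strong binders (Tet-High), weak binders (Tet-Low) and non-binders (Tet-Negative) were sorted from 2 pools of 15 mice each, which gave 2 libraries per group. Transcripts and surface proteins were counted in the same cells. The libraries held 30665197 to 47659534 RNA UMIs on 2979 to 5379 barcodes. Retained CD8 T cells numbered 2817 and 2845 in Tet-High, 2541 and 2864 in Tet-Low, and 4358 and 5025 in Tet-Negative. Their median depth was 10832 and 14454 UMIs per cell in Tet-High, 10025 and 12544.5 in Tet-Low, and 6863 and 6566 in Tet-Negative. Cells in clusters of other types, left out of every comparison, were 6.54% of the cells that passed the filters in Tet-High replicate 1 and 0.73% in Tet-High replicate 2. They were 0.78% and 0.17% in Tet-Low and at most 0.02% in Tet-Negative. After a log2 fold change, ± is the SE of the edgeR fit, and after a mean it is the SD of 2 libraries.

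The first comparison asks how strong binders differed from non-binders of the same tumours. Tet-High cells carried far more transcript for inhibitory receptors, granzymes and inflammatory chemokines and far less for genes of naive, recirculating T cells. Havcr2 (ENSMUSG00000020399), which encodes the inhibitory receptor Tim-3, averaged 132 ± 11.2 CPM in Tet-High and 1.67 ± 1.4 CPM in Tet-Negative, a log2 fold change of 6.32 ± 0.47 (adjusted p = 6.27e-05, edgeR). Gzmf (ENSMUSG00000015441), a granzyme of activated killer cells, averaged 382 ± 115 against 2.65 ± 2.6 CPM, a log2 fold change of 7.18 ± 0.82 (adjusted p = 0.00038). S1pr1 (ENSMUSG00000045092), which encodes the receptor for exit from lymphoid tissue, averaged 5.69 ± 0.817 against 155 ± 31.2 CPM, a log2 fold change of -4.77 ± 0.21 (adjusted p = 1.76e-05). The 10 most raised genes, with log2 fold changes of 5.82 to 7.18 and one direction in both pools, also held Gzmc (ENSMUSG00000079186), Gzme, the chemokine genes Ccl1 (ENSMUSG00000020702) and Ccl3, Fcer1g (ENSMUSG00000058715), which encodes a signalling chain of Fc and NK receptors, the transporter gene Slc16a11 (ENSMUSG00000040938), Epdr1 and AC163354.1. The most lowered, at -4.88 to -4.49, were Rapgef4 (ENSMUSG00000049044), Igfbp4 (ENSMUSG00000017493), Tmem108, Treml2, S1pr1, Il6ra, Auts2, Tdrp and Dtx1. In all, 7354 of 12510 genes differed, 3760 higher and 3594 lower, of which 2038 and 1919 by at least 2-fold. As checks of the sort, Cd3e did not pass the test at -0.09 ± 0.12 (adjusted p = 0.537), Cd8b1 was lower, at -0.54 ± 0.12 (adjusted p = 0.00786), and Cd8a was higher, at 0.64 ± 0.12 (adjusted p = 0.00291). Cd4 fell to the filter on low counts. Naive-like cells made up 82.4 ± 4.21% of Tet-Negative and 7.68 ± 3.75% of Tet-High cells, and without them 4471 genes differed (an alternative chosen after seeing the data). The other Tet-Negative cells still held Lef1, a gene of naive cells, at 141.5 and 151.8 CPM, against 8.8 and 7.2 in the other Tet-High cells. That setting thus does not take all naive-like expression out of the comparisons with Tet-Negative.

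**Figure D1:**
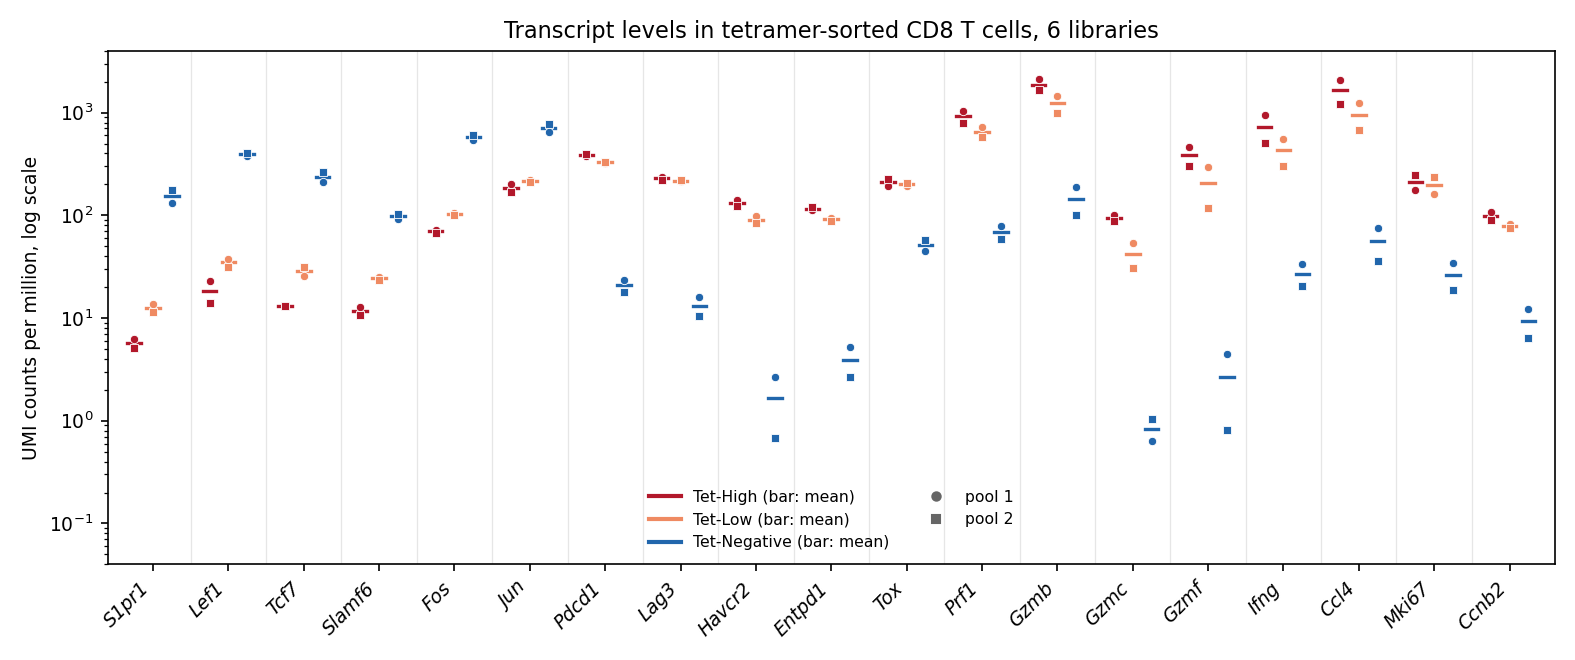
Transcript levels (CPM, log axis) of 19 genes in the 6 libraries, with a circle for pool 1, a square for pool 2 and a bar for the mean of each group. S1pr1 averaged 5.69 CPM in Tet-High, 12.5 in Tet-Low and 155 in Tet-Negative, and Havcr2 averaged 132, 90.8 and 1.67.

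Among inhibitory receptors, 9 of 12 rose in Tet-High cells and 2 fell, the same counts when adjusted over the list alone. Pdcd1, which encodes PD-1, rose by 4.22 ± 0.17 on the log2 scale, Lag3 by 4.12 ± 0.21, Tigit by 4.13 ± 0.27 and Entpd1, which encodes the ectonucleotidase CD39, by 4.90 ± 0.28. Btla changed by -2.15 ± 0.16. The list median was 3.21 (camera adjusted p = 9.32e-09, adjusted p = 0.207 with an estimated correlation). Of 15 exhaustion transcription factors, 11 rose and 2 fell (12 and 2 adjusted over the list alone, median 2.04). Tox, a driver of the exhausted state, rose by 2.04 ± 0.17 and Nr4a2 by 3.17 ± 0.14, while Nr4a1, induced by receptor signalling, changed by -1.23 ± 0.22 and Eomes by -1.08 ± 0.35. The camera adjusted p was 1.79e-06 (adjusted p = 0.0945 with an estimated correlation). Cytotoxic granule genes rose in 13 of 16 cases and none fell (14 higher and 1 lower adjusted over the list alone, median 3.30, camera adjusted p = 5.22e-08, adjusted p = 0.207 with an estimated correlation). They included Prf1, which encodes perforin, at 3.73 ± 0.22, and Gzmb, which encodes granzyme B, at 3.69 ± 0.35. Of 16 cytokine and chemokine genes, 12 rose by either count and the others did not pass (median 4.19, camera adjusted p = 1.51e-06, adjusted p = 0.217 with an estimated correlation). Ifng rose by 4.75 ± 0.46, Ccl4 by 4.88 ± 0.50 and Spp1 by 5.69 ± 0.49, whereas Tnf stood at 0.25 and Il2 at 0.96 without passing.

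Every one of the 18 naive and central memory genes fell in Tet-High cells by either count (median -3.65, camera adjusted p = 2.4e-34, adjusted p = 0.0828 with an estimated correlation). Tcf7, which encodes the stem-like factor TCF-1, changed by -4.17 ± 0.18, and Lef1, S1pr1 and Ccr7 fell with it. Progenitor exhausted genes split, 8 of 12 lower and 2 higher by either count (median -2.42, camera adjusted p = 3.87e-05, adjusted p = 0.207 with an estimated correlation). Slamf6, a surface marker of progenitor cells, changed by -3.07 ± 0.14, while the chemokine gene Xcl1 rose by 2.48 and Cd200 by 3.45. Tissue residency genes had 7 of 11 higher and 3 lower by either count, with a median of 1.58 and no list call (camera adjusted p = 0.0569, or 0.0333 with the pool as a block, adjusted p = 0.217 with an estimated correlation). Cxcr6, a chemokine receptor of tissue T cells, rose by 3.15 ± 0.17 and Itga1 by 3.86, and Itgae, which encodes the integrin CD103, changed by -2.81 ± 0.39. Effector memory genes went both ways, 6 higher and 5 lower of 14 (7 and 5 adjusted over the list alone, median 1.27, camera adjusted p = 0.499, adjusted p = 0.778 with an estimated correlation). Cx3cr1, a receptor of effector cells, rose by 4.54 ± 0.28 and Itgb7, which encodes a gut homing integrin, changed by -3.39 ± 0.16.

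All 24 proliferation genes rose by either count (median 2.75, camera adjusted p = 5.62e-11, adjusted p = 0.231 with an estimated correlation). Mki67, a marker of cycling cells, rose by 3.0 ± 0.34 and Ccnb2, a mitotic cyclin gene, by 3.40. Glycolysis genes rose in 15 of 18 cases and 1 fell by either count (median 1.30, camera adjusted p = 5.59e-06, adjusted p = 0.207 with an estimated correlation). Ldha, lactate dehydrogenase, rose by 1.56 ± 0.15 and Tpi1 by 2.59 ± 0.18, and Pdk1, whose kinase restrains pyruvate use by mitochondria, changed by -1.69. Oxidative phosphorylation genes rose in 11 of 23 cases and 1 fell by either count (median 0.43, camera adjusted p = 0.0459, or 0.0533 without cycling cells, adjusted p = 0.747 with an estimated correlation), with Cox5a at 1.37 and Sdha at -0.31. Mitochondrially encoded genes fell in 10 of 11 cases by either count (median -0.74, camera adjusted p = 0.015, adjusted p = 0.359 with an estimated correlation), with mt-Co1 at -1.02 ± 0.25.

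TCR activation genes moved apart, 11 of 20 higher and 7 lower (12 and 7 adjusted over the list alone, median 1.36, camera adjusted p = 0.000353, adjusted p = 0.207 with an estimated correlation). Tnfrsf9, which encodes the costimulatory receptor 4-1BB, rose by 4.38 ± 0.31 and Tnfrsf4, which encodes OX-40, by 4.02. The early activation genes Myc and Cd69 changed by -1.37 ± 0.15 and -1.45 ± 0.15. Of 15 immediate early and heat shock genes, 11 fell and 1 rose by either count (median -1.37, camera adjusted p = 0.000116, adjusted p = 0.207 with an estimated correlation). Fos changed by -3.04 ± 0.13 and Jun by -1.95 ± 0.15, both AP-1 subunit genes that also respond to handling of cells, and Atf3 rose by 2.30 ± 0.27. Type I interferon response genes had 9 of 21 lower and 3 higher by either count (median -0.48, camera adjusted p = 0.0512, or 0.0433 with the pool as a block, adjusted p = 0.367 with an estimated correlation). NK-type receptor genes rose in 11 of 13 cases and 2 fell by either count (median 3.69, camera adjusted p = 3.38e-08, adjusted p = 0.212 with an estimated correlation), with the lectin receptor genes Klre1 at 4.41 ± 0.21 and Klrc1 at 3.69 ± 0.28. MHC class II and myeloid genes, which mark other cell types, rose in 11 of 12 cases by either count (median 3.51, camera adjusted p = 0.000194, adjusted p = 0.207 with an estimated correlation). Most stood at low levels: the macrophage gene Lyz2 at 2.94 against 0.0489 CPM and the class II chain gene Cd74 at 3.71 against 0.488 CPM. Tyrobp, a signalling chain gene of NK and myeloid cells on both lists, rose by 3.46 ± 0.26, and the macrophage gene Apoe stood at -0.25 without passing.

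The second comparison asks whether weak binders differed from non-binders. Transcripts of inhibitory receptors, granzymes and chemokines were higher in Tet-Low than in Tet-Negative cells, and those of naive cells lower. Havcr2 averaged 90.8 ± 10.3 CPM in Tet-Low, a log2 fold change of 5.77 ± 0.46 over Tet-Negative (adjusted p = 0.000124, edgeR), Gzmf rose by 6.30 ± 0.80 and Spp1 (ENSMUSG00000029304), which encodes the secreted protein osteopontin, by 5.35 ± 0.48. S1pr1 changed by -3.63 ± 0.20 and Lef1 (ENSMUSG00000027985), a transcription factor of naive T cells, by -3.50 ± 0.25. The 10 most raised genes, at 5.22 to 6.30, also held Slc16a11, Gzmc, AC163354.1, Epdr1, Fcer1g, Serpinb9b (ENSMUSG00000021403) and Fcrl6 (ENSMUSG00000070504). The most lowered, at -4.44 to -3.49, were Rapgef4, Igfbp4, Auts2, Il6ra, Tmem108, Dtx1, S1pr1, Lef1 and Tdrp. In all, 6390 genes differed, 3274 higher and 3116 lower, of which 1873 and 1481 by at least 2-fold. Cd3e stood at -0.03 (adjusted p = 0.845), Cd8b1 was lower, at -0.42 (adjusted p = 0.0246), and Cd8a higher, at 0.52 (adjusted p = 0.00863). Naive-like cells were 8.81 ± 1.95% of Tet-Low cells. Without them the count was 3003, and without Tet-Negative replicate 2 it was 4008.

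By group, 9 of 12 inhibitory receptors rose in Tet-Low cells and 2 fell by either count (median 2.88, camera adjusted p = 1.2e-10, adjusted p = 0.207 with an estimated correlation). Pdcd1 rose by 3.98 and Entpd1 by 4.55. Exhaustion factors rose in 11 of 15 cases and 1 fell by either count (median 1.92, camera adjusted p = 6.53e-08, adjusted p = 0.0828 with an estimated correlation). Granule genes rose in 14 of 16 cases by either count (median 2.99, camera adjusted p = 3.38e-08, adjusted p = 0.207 with an estimated correlation), and cytokine genes in 11 of 16 (12 adjusted over the list alone, median 3.98, camera adjusted p = 7.4e-08, adjusted p = 0.207 with an estimated correlation). All 18 naive and central memory genes fell by either count (median -2.85, camera adjusted p = 1.37e-31, adjusted p = 0.0828 with an estimated correlation). Progenitor exhausted genes had 7 of 12 lower and 2 higher by either count (median -1.60, camera adjusted p = 0.00147, adjusted p = 0.207 with an estimated correlation). All 24 proliferation genes rose by either count (median 2.53, camera adjusted p = 1.22e-11, adjusted p = 0.23 with an estimated correlation), as did 15 of 18 glycolysis genes while 1 fell (median 1.19, camera adjusted p = 3.5e-06, adjusted p = 0.207 with an estimated correlation). Residency genes passed as a list, 7 higher and 3 lower of 11 by either count (median 1.53, camera adjusted p = 0.0118, adjusted p = 0.207 with an estimated correlation). TCR activation genes were 11 higher and 7 lower by either count (median 1.34, camera adjusted p = 5.69e-05, adjusted p = 0.202 with an estimated correlation). Immediate early genes were 9 lower and 1 higher by either count (median -0.82, camera adjusted p = 0.000238, adjusted p = 0.207 with an estimated correlation). NK-type genes were 11 higher and 2 lower by either count (median 3.51, camera adjusted p = 1.06e-09, adjusted p = 0.207 with an estimated correlation).

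In the remaining lists of that contrast, MHC class II and myeloid genes rose in 11 of 12 cases (11 higher and 1 lower adjusted over the list alone, median 2.98, camera adjusted p = 0.00108, adjusted p = 0.217 with an estimated correlation), and Cd74 stood at 3.21 CPM in Tet-Low. Mitochondrially encoded genes fell in 9 of 11 cases (11 adjusted over the list alone, median -0.79, camera adjusted p = 0.00921, adjusted p = 0.332 with an estimated correlation). Lists without a call were effector memory, with 7 genes higher and 3 lower of 14 (7 and 4 adjusted over the list alone, median 1.45, camera adjusted p = 0.085), oxidative phosphorylation, with 8 of 23 higher (7 adjusted over the list alone, median 0.32, camera adjusted p = 0.142), and interferon response. The last had 4 genes higher and 4 lower of 21 (4 and 2 adjusted over the list alone), a median of -0.10, a mean of 0.01 and a camera adjusted p of 0.914.

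The third comparison asks whether strong and weak binders differed. Progenitor and naive genes tended to lie lower in Tet-High, by folds far smaller than those against Tet-Negative, and so did some interferon response genes. No gene passed the main fit. The calls of these genes as lists were lost with an estimated correlation, under which no list passed in any contrast, and were kept by the rotation test fry. Tcf7 (ENSMUSG00000000782) averaged 13.1 CPM in Tet-High and 28.6 CPM in Tet-Low, a log2 fold change of -1.13 ± 0.16 (adjusted p = 0.128, edgeR). Slamf6 stood at -1.05 ± 0.13 (adjusted p = 0.0801) and Slfn5, an interferon-induced gene, at -1.14 ± 0.12 (adjusted p = 0.0781, the lowest of all). Ifng stood at 0.75 ± 0.40 (adjusted p = 0.946), with 723 against 431 CPM, and Gzmc at 1.17 ± 0.27 (adjusted p = 0.343). Gzmg, a granzyme gene at a low level, stood at 4.21 ± 0.60 (adjusted p = 0.164), with 9.82 against 0.571 CPM. With edgeR and no pool term 0 of 12510 genes passed and 647 had an unadjusted p under 0.05. Tet-High and Tet-Low libraries of a pool deviated together (correlation 0.85), and that fit counts the shared part as error. DESeq2 called 85, of which 83 lower and 2 higher, and the edgeR fit with the pool as a block called 60, of which 57 lower and 3 higher. Tcf7 had an adjusted p of 0.0152 with that block and 1.53e-06 by DESeq2, Slamf6 0.0167 and 2.03e-07, and Slfn5 0.0152 and 6.26e-08. Ifng passed with the block alone of these fits (0.74, adjusted p = 0.0251), as did Ccl4 (0.80, adjusted p = 0.0258), and Gzmc with DESeq2 (1.16, adjusted p = 0.00628). Gzmg passed with both (4.25, adjusted p = 0.0152, and 4.12, adjusted p = 0.0217). Without a filter on low counts edgeR called 146 genes, of which 133 lower and 13 higher. Among the higher were Gzme (1.91, adjusted p = 0.000236), Gzmd (1.72, adjusted p = 0.0032), Gzmc and Gzmg.

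As lists, 10 of 17 passed camera between Tet-High and Tet-Low although 0 members passed over all genes. Naive and central memory genes had 14 of 18 lower adjusted over the list alone (median -0.62, camera adjusted p = 1.76e-35, adjusted p = 0.0828 with an estimated correlation). Interferon response genes had 9 of 21 lower on that count (median -0.33, camera adjusted p = 4.15e-19, adjusted p = 0.0828 with an estimated correlation), with Rsad2, an antiviral gene, at -1.51 ± 0.17. Progenitor exhausted genes had 6 of 12 lower (median -0.64, camera adjusted p = 1.35e-13, adjusted p = 0.0828 with an estimated correlation), and effector memory genes 3 of 14 (median -0.18, camera adjusted p = 1.59e-05, adjusted p = 0.214 with an estimated correlation), with Cxcr3 at -1.13 ± 0.17 and Ly6c2 at -0.93 ± 0.26. Immediate early genes had 1 lower (median -0.26, camera adjusted p = 0.00121, adjusted p = 0.207 with an estimated correlation), with Fos at -0.56 ± 0.12. In the other direction, granule genes had 2 of 16 higher (median 0.26, camera adjusted p = 1.59e-05, adjusted p = 0.231 with an estimated correlation) and MHC class II and myeloid genes 1 of 12 (median 0.65, camera adjusted p = 4.68e-07, adjusted p = 0.207 with an estimated correlation), with Lyz2 at 1.83 ± 0.41. Proliferation (median 0.21, camera adjusted p = 0.000981, adjusted p = 0.547 with an estimated correlation), oxidative phosphorylation (0.15; 0.000797, adjusted p = 0.571 with an estimated correlation) and glycolysis genes (0.15; 0.0232, adjusted p = 0.367 with an estimated correlation) passed upward with 0 members on that count. Inhibitory receptors did not pass (median 0.12, camera adjusted p = 0.305), nor did cytokines (0.07; 0.219, or 0.00188 with the pool as a block), NK-type receptors (0.15; 0.186), residency (-0.04; 0.108), and mitochondrially encoded genes (-0.03; 0.566). Exhaustion factors had a median of 0.06 and a mean of -0.07 (camera adjusted p = 0.914), and TCR activation genes a median of -0.02 and a mean of 0.02 (camera adjusted p = 0.625). The rotation test fry called 3 lists here: naive and central memory (adjusted p = 0.00672), progenitor exhausted (0.00882) and interferon response (0.0183).

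Tet-Low cells were placed between the other groups, on the log2 CPM scale, by genes chosen in one pool and measured in the other. For the genes raised in Tet-High they lay at 0.954 ± 0.013 of the way from Tet-Negative to Tet-High (SD, n = 2 directions of choice), with 0.95 and 0.96. For the genes lowered in Tet-High, which include those of naive cells, they lay at 0.746 ± 0.026, with 0.73 and 0.76. On the CPM scale these positions and their order can differ, and they were not worked out there. No test of these positions was run.

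Of 13 surface proteins tested, 9 differed between Tet-High and Tet-Negative, with inhibitory and costimulatory receptors higher and CD3 and CD5 lower. Tet-High cells carried more Tim-3, at 57.8 ± 16 against 0.371 ± 0.166 tag UMIs per cell (log2 fold change 5.87 ± 1.06, adjusted p = 2.87e-05, edgeR), more PD-1, at 50.1 ± 3.79 against 1.36 ± 0.523 (3.84 ± 0.96, adjusted p = 0.000723), and more CD137 (4.28 ± 0.93), LAG-3 (3.90 ± 0.94), CD25, the high-affinity interleukin receptor chain (3.24 ± 0.90), and OX-40 (1.89 ± 0.80). Lower were CD3, at 16 ± 4.12 against 42 ± 11.2 (-2.45 ± 0.90, adjusted p = 0.018), and CD5, a negative regulator of receptor signalling (-1.84 ± 0.80, adjusted p = 0.0384, or 0.0646 with the pool as a block). Tet-Low differed from Tet-Negative in 7 proteins, among which Tim-3 (5.38), CD137 (3.81), LAG-3 (3.65), PD-1 (3.64) and CD25 (2.98) were higher, and CD3 (-2.47) was lower. OX-40 was lost by total tag count (adjusted p = 0.121), by the RNA library size (0.244) and in every fit without 1 library (0.104 to 0.598) except that without Tet-Negative replicate 2. CD3 was lost in both contrasts without Tet-Low replicate 1 (adjusted p = 0.0577 and 0.202) and without Tet-High replicate 2 (0.078 and 0.05), and CD5 without those libraries and by the RNA library size (0.0793). With the pool as a block KLRG1 also passed in both contrasts (1.53, adjusted p = 0.00417, and 1.48, adjusted p = 0.00509), and OX-40 passed in Tet-Low (adjusted p = 0.00509). KLRG1 passed by total tag count too (adjusted p = 0.00986 and 0.01) and per cell (0.0148 and 0.0176), but not by the RNA library size (0.192 and 0.183). Between Tet-High and Tet-Low edgeR called 0 proteins under each of the 4 scalings, with 0 at an unadjusted p under 0.05 and every adjusted p at 0.99 with TMM. The highest isotype control, mouse IgG1, stood at 0.171 UMIs per cell in Tet-High, 0.143 in Tet-Low and 0.0334 in Tet-Negative.

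The protein folds depended on the scaling. The TMM factors of the tags were 0.508 and 1.27 in the Tet-Negative libraries, and the tag UMIs per cell were 934.2 and 749.3 in Tet-High, 938.2 and 695.1 in Tet-Low, and 567.5 and 534.7 in Tet-Negative. With the number of cells as the library size, the median protein fold rose by 1.24 on the log2 scale for Tet-High and 1.13 for Tet-Low against Tet-Negative. By total tag count the shifts were 0.60 and 0.57, and by the RNA library size 0.22 and 0.10. CD44, an activation marker at 392 ± 65.5 against 98 ± 19.5 UMIs per cell, stood at 0.70 (adjusted p = 0.412) with TMM and at 2.0 (adjusted p = 0.000771) per cell. By total tag count it stood at 1.39 (adjusted p = 0.000255) and by the RNA library size at 0.95 (0.214). In Tet-Low, CD5 passed by total tag count alone of these scalings (-0.97, adjusted p = 0.00166). In Tet-High, CD5 stood at -0.55 (adjusted p = 0.225) per cell, and CD3 stayed lower at -1.39 (adjusted p = 0.0235).

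**Figure D2:**
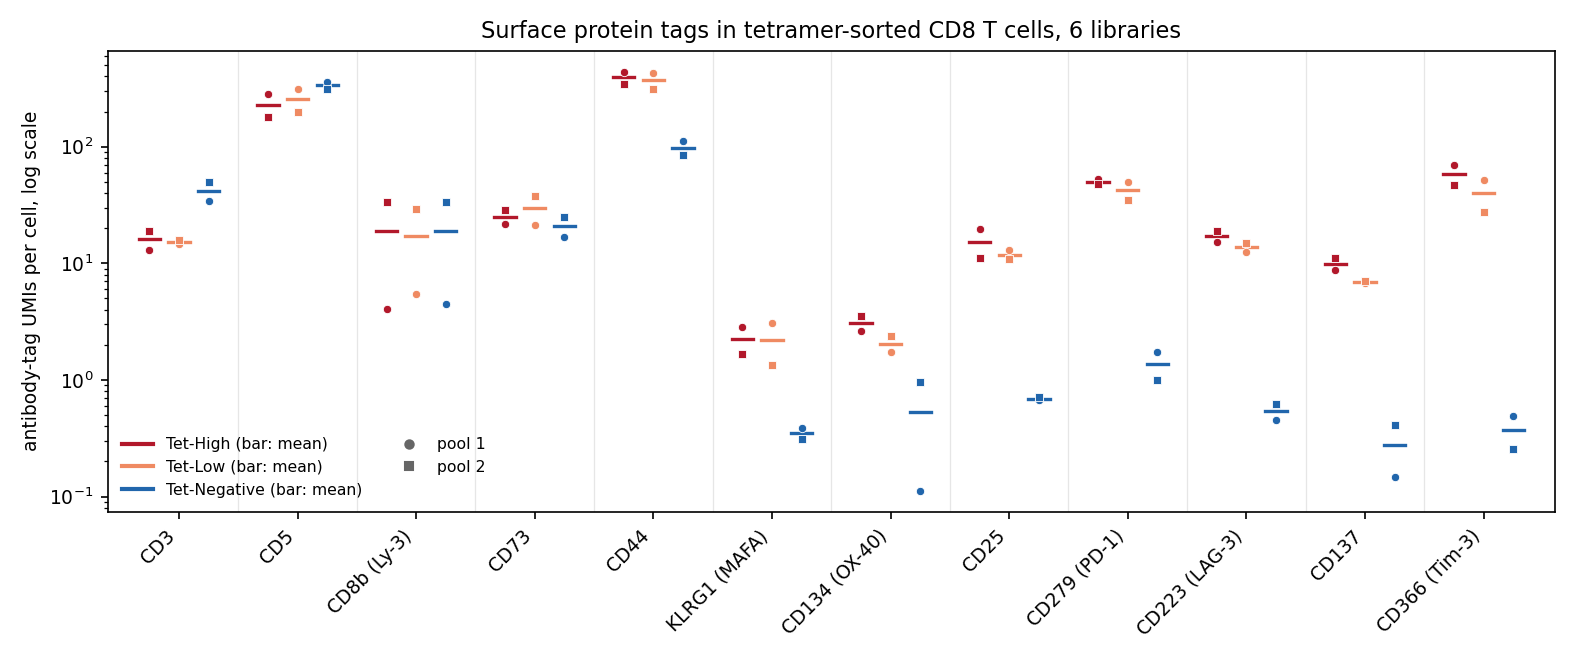
Antibody-tag UMIs per retained cell (log axis) for 12 of the 13 antibodies tested in the 6 libraries, with a circle for pool 1, a square for pool 2 and a bar for the group mean. Tim-3 averaged 57.8 UMIs per cell in Tet-High, 40 in Tet-Low and 0.371 in Tet-Negative, and CD3 averaged 16, 15.2 and 42.

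Cell states were compared by shares of a clustering that did not use the genes called against Tet-Negative. Its clusters are named by leading genes over all genes, which include genes left out of the clustering. Among genes not left out, Gm26917 and Gm10073 led the cluster named by Lef1, and Gm10076 and Gm10260 that named by Igfbp4. Clusters led by Lef1 and by Igfbp4, genes of naive cells, held 44 ± 8.62% and 37.6 ± 15.3% of Tet-Negative cells but 5.6 ± 1.71% and 5.61 ± 3.76% of Tet-High cells (SD, n = 2; log2 fold changes -2.97 ± 0.74 and -2.74 ± 0.72, adjusted p = 0.000893 and 0.00125, edgeR). Mitotic cells, led by Ube2c and histone genes, were 14.9 ± 2.07% of Tet-High and 0.862 ± 0.403% of Tet-Negative (4.11 ± 0.58, adjusted p = 3.33e-06). Cells led by Gzmc and Gzmf were 14.1 ± 5.04% against 2.87 ± 0.153% (2.29 ± 0.52, adjusted p = 0.000401), and those led by the replication genes Mcm3 and Mcm6 were 17.3% against 1.5% (3.53 ± 0.60). An interferon cluster, led by Isg15 and Ifit3, held 6.59 ± 0.471%, 11.2 ± 0.917% and 6.01 ± 1.4% of Tet-High, Tet-Low and Tet-Negative cells and did not pass in any contrast (adjusted p = 0.83, 0.068 and 0.774). In both contrasts with Tet-Negative 8 of 10 clusters differed. The cluster led by Fgl2 and Ahnak was lost with the pool as a block (adjusted p = 0.193 for Tet-High and 0.102 for Tet-Low). Between Tet-High and Tet-Low edgeR called 0 clusters, with 0 at an unadjusted p under 0.05 and every adjusted p at 0.774. In the planned classes, which rest on genes that separate the groups, interferon-responding cells were 3.84 ± 1.67%, 5.09 ± 1.24% and 1.35 ± 0.136% of Tet-High, Tet-Low and Tet-Negative, and both contrasts with Tet-Negative passed (1.51 ± 0.51, adjusted p = 0.0119, and 1.91 ± 0.51, adjusted p = 0.00282). The Tet-High call was lost at resolution 1.5, without Tet-High replicate 2 and without either Tet-Negative library, and turned at resolution 0.5 (-1.39, adjusted p = 0.0169). The Tet-Low call was lost at resolution 0.5 and without either Tet-Negative library. Among those classes, cycling cells were 31.6 ± 0.421%, 24.2 ± 0.388% and 1.3 ± 0.854% of Tet-High, Tet-Low and Tet-Negative. They did not pass between Tet-High and Tet-Low (0.38, adjusted p = 0.699) but did without either Tet-Negative library. At resolution 0.5, 3 of the planned classes differed between Tet-High and Tet-Low. Unnamed clusters took 12.68 to 58.73% of the cells that passed the filters, and their shares were not tested. One led by Ccl5, Cxcr3 and Gzma held 110 and 72 Tet-High but 248 and 244 Tet-Low cells. Another, led by Eno3 and Mcm6, held 604 and 614 Tet-High but 314 and 373 Tet-Low cells. The 0 calls between Tet-High and Tet-Low thus do not show an equal make-up.

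**Figure D3:**
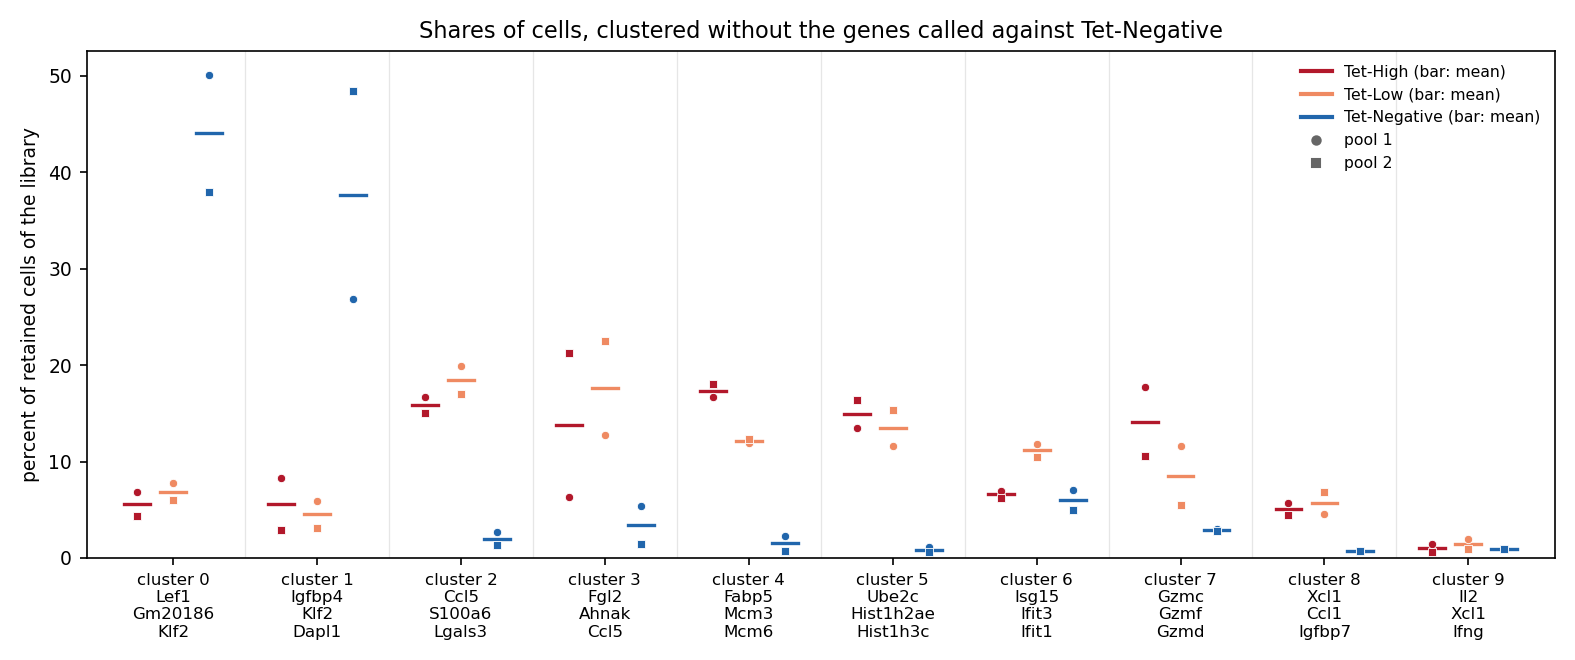
Percent of the retained cells of each library in 10 clusters made without the genes called against Tet-Negative, with a circle for pool 1, a square for pool 2, a bar for the group mean, and 3 of its leading genes under each cluster. Leading genes were ranked over all genes, those left out of the clustering included. The cluster led by Lef1 held 44% of Tet-Negative and 5.6% of Tet-High cells, and the cluster led by Ube2c held 0.862% and 14.9%.

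Within single classes the groups still differed. Naive-like cells of Tet-High carried more S100a4 (ENSMUSG00000001020), a calcium-binding protein gene of antigen-experienced T cells, at 3.34 ± 0.24, and Gzmb at 2.17 ± 0.30, while naive-like cells of Tet-Low carried more S100a4 at 3.29 ± 0.22, Ikzf2, which encodes Helios, at 3.18 ± 0.20 and Sox4 at 2.52 ± 0.23. Of 7106 genes, 23 differed between Tet-High and Tet-Negative (10 higher, 13 lower) and 27 between Tet-Low and Tet-Negative (17 and 10), while edgeR called 0 between Tet-High and Tet-Low, with 333 at an unadjusted p under 0.05. The other cells of Tet-High replicate 1 held Gzmb at 2152.9 CPM, against 22.8 CPM in its naive-like cells. Free RNA was not measured. At 1.06% of the level of the other cells (1.4% in replicate 2) it would give all the Gzmb of these cells, so their higher Gzmb is not read as their own. Such a share was not worked out for the other genes or for Tet-Low. Whether those transcripts are the cells' own stays open. With the pool as a block the counts were 74, 108 and 7. They also moved when single libraries were left out: against Tet-Negative the Tet-High count was 2 and 1 without Tet-High replicate 1 and 2, 7 without either Tet-Low library, and 49 and 36 without Tet-Negative replicate 1 and 2. The Tet-Low count was 17 without Tet-High replicate 2, 3 and 7 without Tet-Low replicate 1 and 2, and 69 and 45 without Tet-Negative replicate 1 and 2. Between Tet-High and Tet-Low it was 7 without either Tet-Negative library.

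Interferon-responding cells of Tet-High had Havcr2 higher by 4.70 ± 0.48 and Lef1 changed by -5.06 ± 0.41 against those of Tet-Negative, and in Tet-Low Havcr2 was 4.20 and Lef1 -2.52 ± 0.29. Of 6664 genes, 981, 622 and 12 differed in the 3 contrasts (1607, 1267 and 60 with the pool as a block). Between Tet-High and Tet-Low 11 were lower, among them Lef1 at -2.54 ± 0.48 (adjusted p = 0.042), Tcf7 at -2.30 (adjusted p = 0.0493) and Trim30c at -2.20 (adjusted p = 0.00197), and Tyrobp was higher at 3.41 ± 0.61, on 9 and 54 UMIs in Tet-High and 1 and 6 in Tet-Low. This class joined a cluster with 64 and 133 Tet-High but 9 and 1 Tet-Negative cells to another with 11 and 10 Tet-High but 54 and 62 Tet-Negative cells, so its mixture differed between groups. Without Tet-Negative replicate 2 the counts were 473, 199 and 5. The Tet-High count against Tet-Negative was 638 without Tet-High replicate 2, the Tet-Low count was 380, 386 and 391 without Tet-Low replicate 1, Tet-Low replicate 2 and Tet-Negative replicate 1, and the count between Tet-High and Tet-Low was 6 without Tet-High replicate 2 and 5 without Tet-Negative replicate 1. An unnamed cluster led by Cxcr3, Gzma, Ly6c2 and Ccr2, genes of effector memory cells, was tested by its number after the data were seen. Of its 8094 genes, 52, 55 and 1 differed in the 3 contrasts (171, 184 and 3 with the block). Gzma was higher by 2.50 ± 0.34 in Tet-High and 1.93 ± 0.33 in Tet-Low, Dapl1, a gene of naive cells, stood at -1.70 ± 0.25 and -1.31 ± 0.20, and Tyrobp was the single gene between Tet-High and Tet-Low, with 19 and 10 UMIs against 2 and 0. Its counts against Tet-Negative reached 84 and 86 without Tet-High replicate 1. For Tet-Low they were 91 without Tet-High replicate 2, 14 and 24 without Tet-Low replicate 1 and 2, and 28 without Tet-Negative replicate 2. Between Tet-High and Tet-Low they were 4 without Tet-High replicate 1 and 0 without Tet-Low replicate 2.

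V beta use, read from 653 to 1873 Trbv UMIs per library, gave 0 calls among 20 Trbv genes in every contrast by edgeR, with 5, 1 and 1 genes at an unadjusted p under 0.05. Trbv2 (ENSMUSG00000076462) took 8.05 ± 0.772% of Trbv UMIs in Tet-High, 18.1 ± 2.54% in Tet-Low and 16.7 ± 1.47% in Tet-Negative (adjusted p = 0.188 for Tet-High against Tet-Negative and 0.282 against Tet-Low). Trbv1 (ENSMUSG00000076461) took 30.9% (exact 95% interval 27.4 to 34.6%) in Tet-High replicate 1 and 2.5% (1.8 to 3.3%) in Tet-High replicate 2. Between Tet-High and Tet-Negative 4 genes differed without Tet-High replicate 1 and 3 without Tet-High replicate 2. Without Tet-High replicate 2, 1 gene, Trbv15, differed between Tet-Low and Tet-Negative and 1, Trbv1, between Tet-High and Tet-Low (3.0, adjusted p = 0.000432). Segments as alike as those of the Trbv12 and Trbv13 groups can share reads.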

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

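The tests of carry-over in Tet-Low and of carry-over as the cause of all naive-like Tet-High cells, of few UMIs by the PD-1 tag, and of free Trbv1 RNA, the bounds on free tag, and the use of an exact interval to read the Trav test, were chosen after the result was seen. A test of few UMIs by marker transcripts, set first, was dropped because the class was named by those markers, and the other tests of this part were set first.

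Several signals stood outside the compared measurements and above their level in Tet-Negative. The streptavidin tag, which reads the PE-labelled tetramer itself, averaged 193 UMIs per Tet-High cell (270 and 117 in the 2 libraries), 99.6 and 33.6 in Tet-Low, and 4.36 and 2.01 in Tet-Negative. Tags below the level set for the protein test were CD11b, at 0.414 UMIs per Tet-High cell against 0.0128 and 0.00796 in the Tet-Negative libraries, and Ep-CAM, at 0.608 against 0.0801 and 0.181. The mouse IgG1 isotype control was higher as well, at 0.171 against 0.0334, so background that rose with the group is not told apart from the Ep-CAM signal. Among the cells left out, natural killer cells reached 1.63% of the cells of Tet-High replicate 1 that passed the filters (0.42% in replicate 2). Dendritic cells reached 2.09% (0.03%) and the macrophage or monocyte cluster, which may hold doublets with CD8 T cells, 2.82% (0.28%). In Tet-Negative each of these types was at most 0.02%.

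Naive-like cells were 10.33% and 5.03% of the Tet-High libraries and 10.19% and 7.44% of the Tet-Low libraries. In Tet-Low, carry-over of non-binding cells as the whole cause is argued against by their streptavidin tag, whose median was 41.5 and 25.0 times that of naive-like Tet-Negative cells of the same pool (bound 2), where free tag would need 86.5% and 78.1% of the tag of the other cells (bound 50%). In Tet-High, 33.7% and 18.2% of these cells (exact 95% intervals 28.3 to 39.4% and 12.2 to 25.5%) held at least 50% of the median tag of the other cells, against 0.03% and 0.02% of Tet-Negative ones with free tag at 10% of that median added, which argues against carry-over as the cause of all of them. Their median was 12 and 5 UMIs, 6.0 and 5.0 times that in Tet-Negative, which free tag at 4.8% and 5.4% would give, so carry-over of the others stays open. A reading of activated cells with few UMIs as naive is argued against by the PD-1 tag, which took no part in the clustering, with medians of 1.0 and 0.0 UMIs against 47 and 45 in the other Tet-High cells (a ratio of at most 0.021), and tetramer binding by naive-like cells stays open, untested apart from this.

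Transcripts of myeloid cells were higher in Tet-High than in Tet-Negative cells. Macrophage RNA or doublets as the cause for Fcer1g and Tyrobp are argued against, because the macrophage share these genes would need, 42.9% and 53.7% for Fcer1g and 1.40% and 2.30% for Tyrobp, was at least 6.18 times the median share that C1qa, C1qb, C1qc, Apoe and Lyz2 would need. For those 5 genes the needed shares differed by 23.87 times in pool 1, which argues against one macrophage profile, but that spread rests on Apoe alone, which needed 0.015% and -0.02%. The other 4 needed 0.077 to 0.386%, and Cd74 and H2-Aa 0.149 to 0.217%, so a trace of macrophage RNA stays open for these, with the profile taken from a single cluster of left-out cells. That cluster held Cd8a at 669.2 CPM, against 766.1 and 844.5 CPM in the retained Tet-High cells. Its profile may thus be mixed with CD8 T cell RNA, and all needed shares are rough. Natural killer and dendritic cells as a source were not tested, though their left-out clusters held Tyrobp higher than other cells by folds of 47.8 and 140.68. Tyrobp stood at 11.68 and 17.75 CPM in Tet-High replicates 1 and 2, while those cells were fewer in replicate 2. Expression of Fcer1g and Tyrobp by strongly binding CD8 T cells may account for these 2 genes and was not tested apart from the macrophage shares.

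Trbv1 took 30.9% of Trbv UMIs in Tet-High replicate 1 and 2.5 to 5.4% in the other 5 libraries. A few cells with very many UMIs are argued against, since the 10 cells with the most held 10.9% of the Trbv1 UMIs and no cell held more than 3. Free RNA spread by droplet depth would have put a Trbv1 UMI in 6.1 of the 291 naive-like cells of that library, and 0 were seen, where a count of 0 allows 3. That argues against free RNA by the full counts alone, since at an equal depth of 2000 UMIs per cell 0 of 266 naive-like cells (limit 1.38%) and 1.09% of the other cells bore one, which does not separate them. Growth of 1 or a few clones in the mice of that pool may be the cause and stays open: Trav12-3, the commonest alpha segment, took 27.3% of 22 Trav UMIs in Trbv1-bearing cells (exact 95% interval 10.7 to 50.2%, across the bound of 30%) against 3.9% in the other cells.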

How the results depend on the processing

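Settings without naive-like cells, without the top 5% of cells by UMIs, with every tag, with the number of cells as tag library size or clustered without called genes, and the tests of an unnamed cluster, were chosen after seeing the data. The cause of each change below was not tested. Single genes were counted as unchanged in 12010 values over the alternatives, gained a call in 262, lost one in 332 and turned direction after a main call in 14. For proteins, classes and V genes these numbers were 1018, 39, 25 and 1. An item without a call in the main fit was counted as unchanged also where its direction turned.

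The counts of genes against Tet-Negative fell to 4471 (Tet-High) and 3003 (Tet-Low) without naive-like cells. Between Tet-High and Tet-Low, where the main count was 0, DESeq2 gave 85 genes, no filter on low counts 146, equal numbers of cells 3, no top 5% of cells 8 and no naive-like cells 31. Lists that passed camera fell to 0, 0 and 0 with an estimated correlation, and fry gave 3 between Tet-High and Tet-Low. Testing every tag gave 26 and 23 proteins against Tet-Negative. At resolution 0.5, 3 classes differed between Tet-High and Tet-Low, and clustering without called genes gave 8 and 8 against Tet-Negative. The position of Tet-Low for raised genes was 0.936 with 50 genes each way.

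With the pool as a replicate block, the count between Tet-High and Tet-Low was 60 genes. Within the interferon class the block gave 1607, 1267 and 60 genes, within naive-like cells 74, 108 and 7, and within the unnamed cluster 171, 184 and 3. Apart from these counts and the blocked values given with the results, the block moved no count by more than 1.5 times.

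Some genes called in the main fit turned direction. Without naive-like cells, the Tet-High folds against Tet-Negative became -0.29 for Ccl5, -0.24 for Tnfsf11, 0.21 for Dusp2, -0.98 for Isg20, -0.34 for Ifih1 and -0.27 for Hk2, of which Isg20 alone passed (adjusted p = 0.00126). In Tet-Low they became -0.079 for Ccl5, 0.26 for Dusp2, -0.67 for Isg20, -0.76 for Mx1, -0.32 for Ifih1 and -0.31 for Hk2, and Isg20 passed there too (adjusted p = 0.00954). Without cycling cells Tubb5 became -0.30 in Tet-High and -0.52 in Tet-Low. The interferon class share of Tet-High turned from 1.51 to -1.39 at resolution 0.5 (adjusted p = 0.0169).

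Leaving out 1 library assumes that the lone library of its group varies like the others. The counts in the order Tet-High against Tet-Negative, Tet-Low against Tet-Negative, and Tet-High against Tet-Low then ran from 5237 to 7199, 4008 (without Tet-Negative replicate 2) to 6511, and 0 to 3 (without Tet-Low replicate 1) for genes. They ran from 14 to 16, 14 to 15 and 9 to 12 for lists, 6 to 10, 5 to 10 and 0 to 0 for proteins, and 3 to 4, 3 to 4 and 0 to 1 (cycling cells, without either Tet-Negative library) for classes. Within the interferon class they ran from 473 to 945, 199 to 697 and 5 to 15, within naive-like cells from 1 to 49, 3 to 69 and 0 to 7, and within the unnamed cluster from 37 to 84, 14 to 91 and 0 to 4, with the libraries named in the results. V genes ran from 0 to 4, 0 to 1 and 0 to 1.

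Keeping doublet calls was not run, since none were removed. Trbv UMIs were fewest in Tet-High replicate 1, at 653. Whether depth or the spread between pools limits the V gene test was not tested.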

Other observations

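Surface CD3 and Cd3e transcript did not move together. The CD3 tag was lower on Tet-High than on Tet-Negative cells, at 16 ± 4.12 against 42 ± 11.2 UMIs per cell (SD, n = 2), while Cd3e transcript stood at -0.09 ± 0.12 on the log2 scale (adjusted p = 0.537, edgeR). The CD3 antibody reads the complex that carries the T cell receptor to the surface. With TMM scaling of the tags, transcript and tag folds were close for Havcr2 and Tim-3 (6.32 and 5.87), Pdcd1 and PD-1 (4.22 and 3.84), Lag3 and LAG-3 (4.12 and 3.90), and Tnfrsf9 and CD137 (4.38 and 4.28). They were farther apart for Tnfrsf4 and OX-40 (4.02 and 1.89), Cd5 and CD5 (-0.64 and -1.84) and Nt5e and CD73 (0.02 and -0.80). With the number of cells as library size the tag folds were 7.28 for Tim-3, 5.20 for PD-1, 4.99 for LAG-3 and 5.15 for CD137. They were 2.52 for OX-40, -0.55 for CD5 and 0.26 for CD73. These are folds per cell, while the transcript folds are relative to all RNA UMIs. Retained Tet-High cells held more RNA UMIs than Tet-Negative ones (medians 10832 and 14454 against 6863 and 6566). The per-cell tag folds are thus not on the scale of the transcript folds, and transcript folds per cell were not worked out.

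The CD3 tag also differed by cell state within each library. Its median on naive-like cells was 37 and 50 UMIs in Tet-High, 42 and 48 in Tet-Low and 34 and 50 in Tet-Negative. On the other retained cells it was 6 and 13, 6 and 8, and 18 and 30. These medians were read after the difference in CD3 had been seen and carry no test.

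A hypothesis set before its result was seen held that more surface receptor gives more bound tetramer, so that across cells of a library the streptavidin tag would track the CD3 tag more than the CD5 tag. Spearman's rho with CD3 was 0.07 and 0.04 in Tet-High and Tet-Low of pool 1 and 0.19 and 0.02 in pool 2. With CD5 it was 0.13, 0.10, 0.04 and 0.07 in the same order. The difference was as low as -0.06 and was positive in Tet-High replicate 2 alone, so the test decided neither way. These rho ran over all retained cells, naive-like ones included. In Tet-High those had a higher median CD3 tag than the other cells (37 and 50 against 6 and 13 UMIs). Their median streptavidin tag was lower (12 and 5 against 248 and 93), so the test cannot tell receptor level from cell state. Over the same cells the streptavidin tag tracked PD-1 with rho of 0.39, 0.23, 0.37 and 0.22 and the RNA UMIs of a cell with rho of 0.45, 0.22, 0.33 and 0.19. Cell state enters these values too, since naive-like Tet-High cells had medians of 1.0 and 0.0 PD-1 UMIs, against 47 and 45 in the others. Cells are not independent replicates, and no p-value was computed.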
